A study of Sorghum bicolor with 18 samples.

How the data were processed

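Sorghum (Sorghum bicolor) tiller buds from the first leaf axil were profiled by RNA sequencing in the phytochrome B mutant phyB-1 and in wild type at 6, 7 and 8 days after planting (DAP), with 3 libraries in each of the 6 groups and 18 in all. The labels describe the 3 libraries of a group as biological replicates, from plants raised in a growth chamber, with TRIzol RNA and TruSeq v2 libraries. That kit protocol is named in the labels without any mark of strand, so reads from a gene and an overlapping antisense gene cannot be told apart here. Groups and replicate numbers were taken from the sample titles.

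One table covering all 18 libraries was used. The deposited counts are total transcript reads and unique transcript reads for each of 39441 transcripts of 33032 genes, per the file headers. The deposited RPKM of each transcript, per the file headers, equalled its total reads divided by transcript length and by one depth per library, so RPKM served only to check that the counts were unscaled. The deposited p-values are false discovery rate corrected values of an EDGE test between groups, with a signed linear fold change, per the file headers. The aligner, its settings, the genome build and the annotation release are not given in the sources used here, so coordinates are printed as deposited, with no build named. In all 28486 genes with 1 transcript the unique reads equalled the total reads. The unique column therefore separates transcripts of one gene, and it says nothing about reads shared between similar genes, which stay an open source of error for members of gene families.

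Total transcript reads were summed to genes. Library totals ran from 8475071 to 14483111 reads, and unique reads made up 79.4% to 80.7% of them. Genes were kept by edgeR's filterByExpr with its minimum count of 10 and minimum total count of 15, which left 19655 genes. The main test was edgeR 4.0.16 quasi-likelihood (robust glmQLFit, glmQLFTest, R 4.3.3) on the summed counts with TMM scaling, one mean per group and one spread per gene shared by all 18 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. Normalised read counts are TMM-normalised CPM from edgeR's cpm function. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. The 12 comparisons were phyB-1 against wild type on each day, each pair of days within each genotype, and the difference between genotypes in each of these changes over days (an interaction). Every adjusted p below comes from this edgeR test, run on all libraries or under the setting named with it. Ranges over all alternatives also include values from DESeq2 and, where it was run, edgeR's exact test. The design, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated.

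The pipeline was tested on simulated counts for the real genes with 200 genes changed. These were drawn only from genes above a minimum of expected reads, which was set higher than the filter's. The draws held no effect of the replicate number, and fewer genes were changed than were called between genotypes in the real data. The shares recovered therefore do not give the power over all tested genes. For phyB-1 against wild type at 6 DAP (19288 genes) it recovered 58.2% of genes changed 1.5-fold, 82.1% at 2-fold and 98.5% at 4-fold, with 8 false calls. At 8 DAP (19307 genes) these were 67.2%, 83.6% and 100%, with 10 false calls. For the interaction of 8 against 6 DAP (19306 genes) they were 16.4%, 68.7% and 93.9%, with 7 false calls. In this simulation interactions therefore had less power for small changes than comparisons of 2 groups.

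The table held 0 gene descriptions, and 0 of its gene identifiers matched the reference gene table used here. The files do not pair identifiers with gene names, so the gene lists fixed beforehand (defined by words in gene descriptions) had no members and their tests were not run. For the same reason the rule for named genes was reduced. It asked for the genes with the largest log2 fold change in each direction among those past the threshold, with group libraries that did not overlap and a mean of at least 5 CPM, and its description requirement could not be applied. For interactions, the differences between libraries of the 2 days had to be without overlap between the genotypes. At most 2 identifiers per direction and comparison are given. That is fewer than the plan set, a cut that the missing descriptions did not require. Beyond these, phyB, the teosinte branched 1 (TB1) homologue and the FLOWERING LOCUS T (FT) homologues CN8, CN12 and CN15 had been fixed by identifier. Their names come from that list and not from the deposited table. A sixth gene fixed by identifier, a dormancy-associated homologue, was left out because its 2 identifiers pointed to different genes in the table. The plan also named phyA and phyC, but without identifiers, and they could not be found without descriptions.

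Replicate numbers are shared by the groups. Deviations from group means correlated above 0.1 in every same-numbered pair for phyB-1 against wild type at 7 DAP (lowest 0.22) and 8 DAP (lowest 0.14), for 8 against 7 DAP in phyB-1 (lowest 0.12) and in wild type (lowest 0.23), and for 7 against 6 DAP in wild type (lowest 0.16). In these 5 comparisons the numbers were taken to pair the libraries, on the evidence of the data and not of the labels. The main test did not use this pairing, and a fit with the replicate number as a block is given as an alternative. In phyB-1 at 7 against 6 and 8 against 6 DAP, and in wild type at 8 against 6 DAP, the lowest correlation was 0.081, 0.097 and 0.057. There too all 6 libraries correlated best with their own number. The labels also give replicates 1 and 3 of a group one sequencing index and replicate 2 another, in all 6 groups. Index set below means this split of replicate 2 from replicates 1 and 3, which the labels do not name as a batch. It does not part replicate 1 from replicate 3, as the replicate block does. No libraries were duplicates: the chi-square per degree of freedom between replicates of a group was 3.02 or more over genes with at least 20 reads. Principal components were computed from log2 CPM with a prior count of 2.

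Alternatives covered RLE and upper quartile scaling, DESeq2 1.42.0, edgeR's exact test, no filter, a filter of at least 1 CPM in every library of a group, the compared groups alone, the replicate number as a block, the index set as a covariate, unique reads, an added log2 fold change threshold of 1, and each library left out in turn. Transcript-level testing, thinning of all libraries to the smallest total, leaving out one replicate number in all groups, and the 4 groups of an interaction alone were added after seeing the data. A fold against a group with 0 reads is given as a lower bound against a floor of 3 counts over the group. Such bounds, and the intervals given with 1 to 3 reads in a group, cover counting error only.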

Results

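Transcript abundance was measured in tiller buds of the first leaf axil of phyB-1 sorghum, which lacks functional phytochrome B (a red and far-red light receptor), and of wild type. The series title places the sampled days between bud initiation and either dormancy in phyB-1 or outgrowth in wild type. Buds were taken at 6, 7 and 8 DAP, with 3 biological replicates per genotype and day. The 18 libraries held 8475071 to 14483111 reads in transcripts, and 19655 genes were tested.

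The libraries separated by genotype along the first principal component (40.0% of variance) and mainly by day along the second (27.04%). The first component also shifted with day in phyB-1, from scores of -9.69 to -4.41 at 6 DAP to -73.9 to -61.1 at 8 DAP. Wild-type scores on it ran from 43.3 to 48.5 at 6 DAP and from 26.1 to 52.2 at 8 DAP. Replicate 2 of phyB-1 at 6 DAP stood apart on the third component (6.75% of variance). The fourth component (5.47% of variance) parted replicate 1 of every group, with scores of 7.64 to 29.1, from all other libraries, with scores of -18.3 to -2.32. What sets replicate 1 apart was not tested. Replicate 3 of wild type at 8 DAP differed most from its group, with chi-square values per degree of freedom of 17.4 and 11.5 against the other replicates. The biological coefficient of variation within groups ran from 7.92% in phyB-1 at 8 DAP to 13.6% in wild type at 8 DAP.

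**Figure D1:**
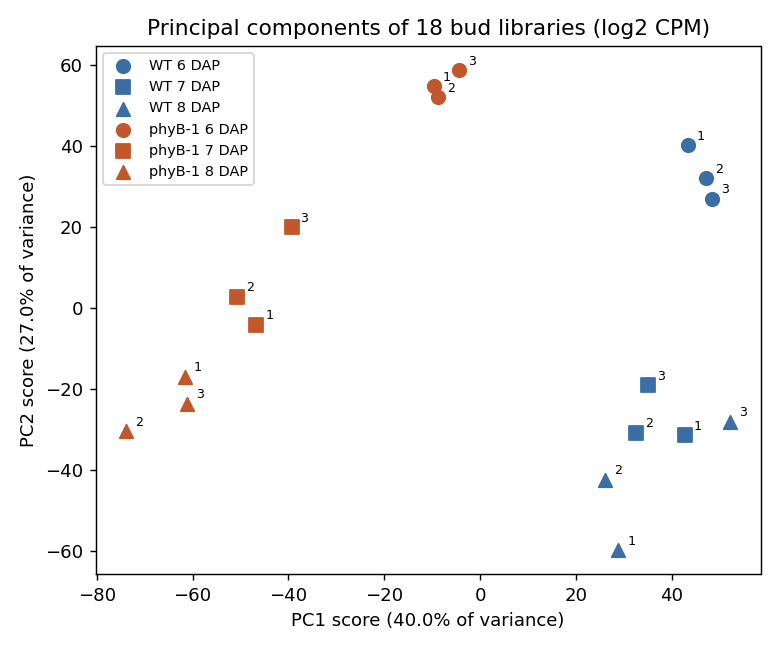
Scores of the 18 libraries on principal components 1 and 2 of log2 CPM, with colour for genotype, marker shape for DAP and the replicate number beside each point. All 9 phyB-1 libraries lie to the left of all 9 wild-type libraries, and the 6 DAP libraries of each genotype lie above its later libraries.

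The mutated gene itself was read in every library. phyB (Sobic.001G394400, Sb01g037340, chromosome 1, 60844250 to 60852774, 4 exons) had 43.9 ± 1.76 CPM in phyB-1 and 57.3 ± 6.00 CPM in wild type at 6 DAP (SD, n = 3 each). Its transcript was lower in phyB-1 at 6 DAP by a log2 fold change of -0.39 ± 0.085 (SE, adjusted p = 0.00422 by edgeR) and at 7 DAP by -0.30 ± 0.083 (adjusted p = 0.0107). Without replicate 3 of every group the 6 DAP call was lost (adjusted p = 0.106, with 0.000291 to 0.106 over all alternatives). The 7 DAP call was lost without replicate 2 or 3 of every group (adjusted p = 0.153 and 0.0578, with 0.00424 to 0.153 over all alternatives). At 8 DAP the log2 fold change was -0.18 ± 0.083 and did not pass the threshold (adjusted p = 0.0961). Across days, phyB libraries ran from 42.2 to 55.3 CPM in phyB-1 and from 51.7 to 63.9 CPM in wild type. Within phyB-1 its level rose from 6 to 8 DAP by a log2 fold change of 0.27 ± 0.085 (adjusted p = 0.0102), a call lost without replicate 3 of every group (adjusted p = 0.0577, with 0.00209 to 0.0577 over all alternatives). The change of the genotype difference between 6 and 8 DAP was not significant (log2 0.21 ± 0.12, adjusted p = 0.271). A gene-level count does not show the sequence of the allele, so these values do not check the genotype labels.

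The TB1 homologue (Sobic.001G121600), a transcription factor gene known to repress bud outgrowth in grasses, was at the detection floor. It had 15 reads over the 9 phyB-1 libraries and 15 over the 9 wild-type libraries, with at most 4 in any library, and was not tested. The FT homologues, members of the florigen family, were also at the floor. CN8 (Sobic.009G199900) had 7 reads in phyB-1 and 6 in wild type, CN15 (Sobic.010G045100) had 5 and 4, and CN12 (Sobic.003G295300) had 0 in both. Differences in these genes were not detectable at this depth.

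The central question of the design was how phyB-1 buds differ from wild-type buds on each day. At 6 DAP the genes with the largest differences were read in one genotype alone. Sobic.010G223800 (chromosome 10, 56344537 to 56349613) had 28.2 ± 2.63 CPM in phyB-1 and 0 reads in wild type, and was at least 268-fold higher in phyB-1 (adjusted p = 4.71e-12). Sobic.001G376100 (chromosome 1, 59268707 to 59271215) had 24.3 ± 2.30 CPM in phyB-1 and 0 reads in wild type, and was at least 232-fold higher (adjusted p = 5.62e-12). In the opposite direction, Sobic.001G375900 (chromosome 1, 59226466 to 59226820) had 23.03 ± 3.07 CPM in wild type and 0 reads in phyB-1, and was at least 265-fold lower in phyB-1 (adjusted p = 1.25e-10). Sobic.001G418300 (chromosome 1, 62732893 to 62734128) had 14.1 ± 1.08 CPM in wild type and 0 reads in phyB-1, at least 163-fold lower (adjusted p = 9.06e-09). In all, 2473 genes passed the threshold at 6 DAP, with 1296 higher and 1177 lower in phyB-1, a near-even split that turned with RLE scaling (1247 higher and 1252 lower) and without replicate 1 of wild type (1021 and 1084). Without replicate 2 or 3 of every group 1053 and 1265 genes passed. The split was less even among the 975 that also differed at least 2-fold, with 675 higher and 300 lower.

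**Figure D2:**
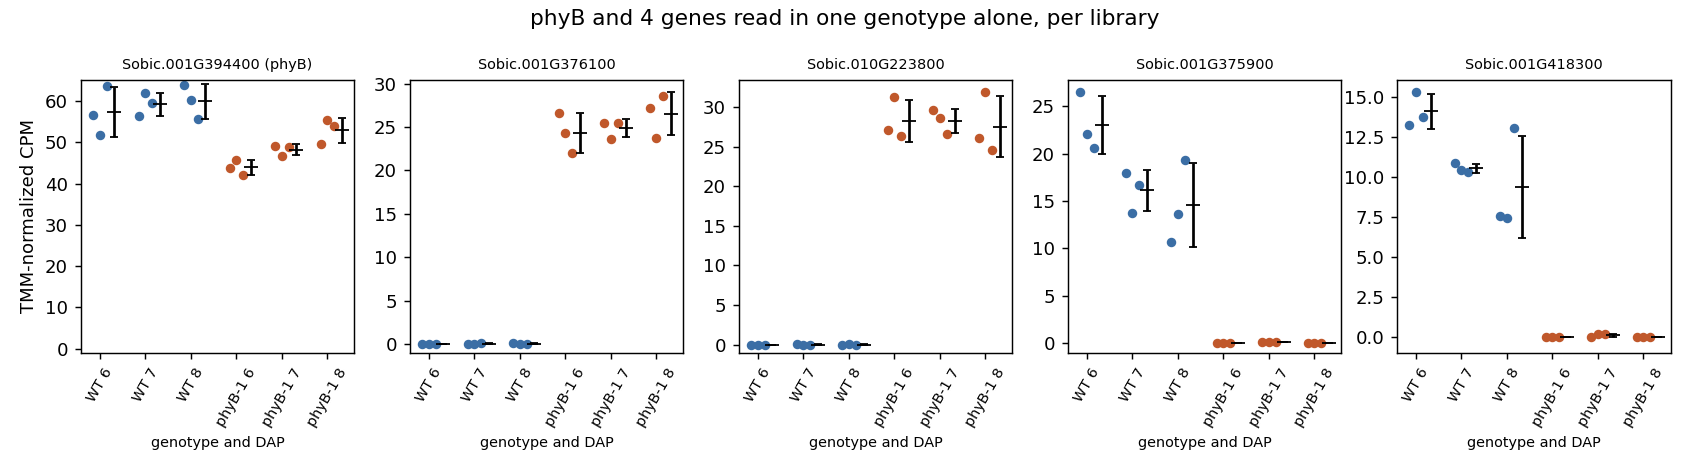
TMM-normalised CPM per library of phyB and 4 genes read in one genotype alone, against genotype and DAP, with points for libraries and bars for the mean ± SD of 3. phyB runs from 42.2 to 63.9 CPM, and each of the other 4 genes stays at or below 0.17 CPM in all 9 libraries of one genotype and at or above 7.44 CPM in all 9 of the other.

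At 7 DAP 5687 genes passed the threshold, with 2693 higher and 2994 lower in phyB-1, a split that turned with upper quartile scaling (2984 higher and 2758 lower). Sobic.010G223800 and Sobic.001G376100 again differed most upward, with 28.2 ± 1.53 CPM and 24.9 ± 1.05 CPM in phyB-1 and 1 read each over the 3 wild-type libraries. Their ratios were 1070 (95% counting interval 192 to 42300) and 943 (169 to 37300). Most reduced was Sobic.K041000 (scaffold super_67, 28743 to 32706), with 21.5 ± 5.90 CPM in wild type and 1 read in phyB-1, a ratio of 840 (150 to 33200, adjusted p = 8.48e-09). Sobic.010G031200 (chromosome 10, 2522143 to 2523314) followed with 12.4 ± 3.40 CPM in wild type and 1 read in phyB-1, a ratio of 474 (84.6 to 18800, adjusted p = 9.66e-07). Of the called genes 1638 differed at least 2-fold, 783 upward and 855 downward. With the replicate number as a block 6532 genes passed. Without replicate 1 or 2 of every group the counts were 3729 and 2722, and the latter leaves replicates 1 and 3, which share a sequencing index within each group.

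At 8 DAP 8475 genes passed the threshold, with 3751 higher and 4724 lower in phyB-1, a split that turned with upper quartile scaling (4514 higher and 4067 lower). Sobic.K041000 reached 32.2 ± 5.64 CPM in wild type against 2 reads in phyB-1, a ratio of 632 (175 to 5230, adjusted p = 1.68e-09). Its wild-type level was still low at 6 DAP (2.01 ± 1.40 CPM), while in phyB-1 it was near silent from the start (4 reads at 6 DAP). Sobic.001G375900 had 14.6 ± 4.39 CPM in wild type and 1 read in phyB-1, a ratio of 591 (106 to 23400, adjusted p = 2.01e-10). Sobic.010G223800 and Sobic.001G376100 held at 27.5 ± 3.84 and 26.5 ± 2.47 CPM in phyB-1. Of the called genes 2316 differed at least 2-fold, 1175 upward and 1141 downward. With the replicate number as a block 9290 genes passed, and without replicate 2 or 3 of every group 5477 and 5116.

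Genotype differences overlapped between days, which were measured in separate libraries, by more than independent lists would. Of the genes higher in phyB-1 at 6 DAP, 836 were also higher at 7 DAP, where 178 would be shared by independent lists, and 901 of those lower were also lower (179 for independent lists). Between 7 and 8 DAP the shared genes were 2062 higher (514 for independent lists) and 2527 lower (720 for independent lists). Of the 10019 genes called on at least 1 day, 1551 were called in the same direction on all 3 days, 763 higher and 788 lower in phyB-1, and 110 were called in both directions on different days. Across genes the log2 fold changes correlated with r = 0.64 between 6 and 7 DAP, 0.86 between 7 and 8 DAP and 0.58 between 6 and 8 DAP. These coefficients are across genes, which are not independent replicates. Within 5 Mb of phyB 95 of 761 tested genes (12.5%) were called in the same direction on all 3 days, against 1456 of 18894 (7.71%) elsewhere.

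**Figure D3:**
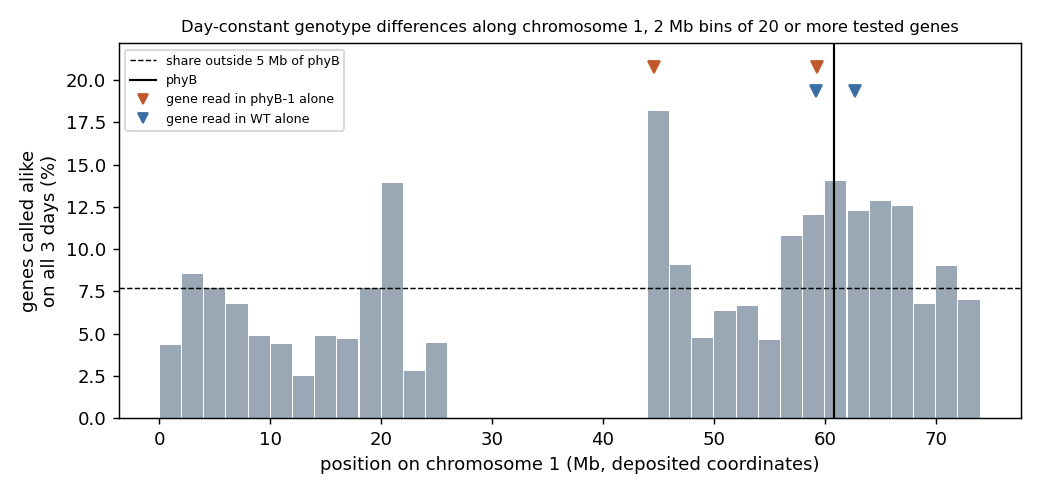
Percent of tested genes called in the same direction on all 3 days in 2 Mb bins along chromosome 1 (deposited coordinates in Mb; bins with at least 20 tested genes), with the share outside 5 Mb of phyB as a dashed line, phyB as a vertical line and triangles at genes read in one genotype alone. The bin that holds phyB reaches 14.04% and the dashed line lies at 7.71%. The bin that starts at 44000001 is higher, at 18.18% (4 of 22 tested genes), and the one that starts at 20000001 reaches 13.89%.

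**Figure D4:**
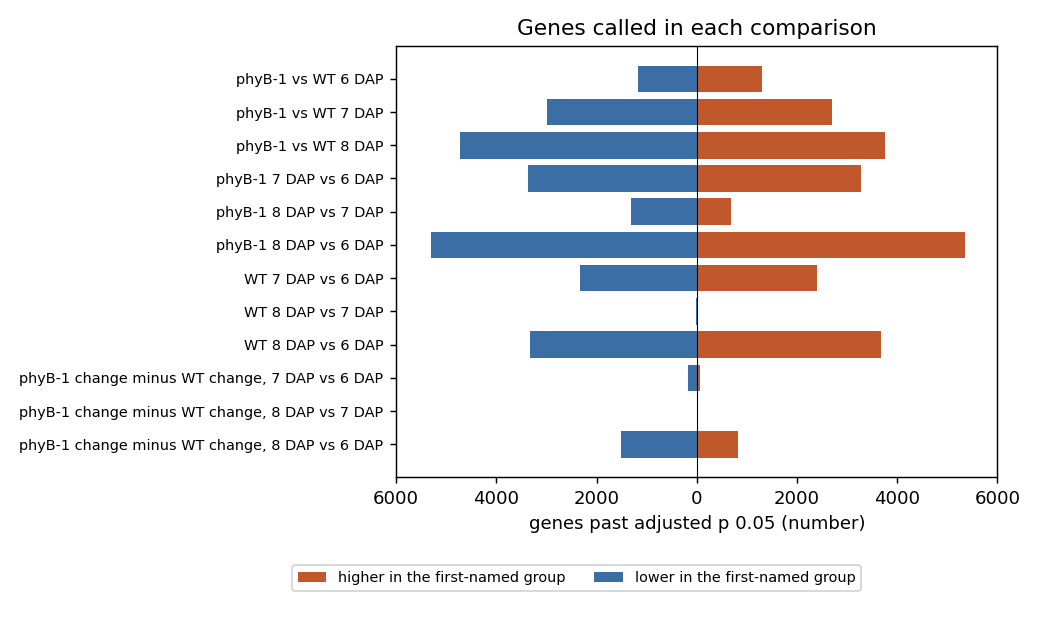
Number of genes past adjusted p 0.05 in each of the 12 comparisons, with genes higher in the first-named group to the right of 0 and lower genes to the left. For the 3 comparisons at the bottom, right means a more positive change over days in phyB-1 than in wild type. Genotype calls number 2473, 5687 and 8475 at 6, 7 and 8 DAP, and wild type at 8 against 7 DAP has 27.

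The second question was how buds of each genotype changed over the days. In wild type from 6 to 7 DAP, Sobic.008G049200 (chromosome 8, 4820963 to 4821912) rose from 0.529 ± 0.24 to 14.03 ± 3.40 CPM, 26.5-fold (adjusted p = 0.0019). Sobic.009G145200 (chromosome 9, 50264495 to 50266102) rose from 1.34 ± 0.40 to 17.2 ± 5.85 CPM (adjusted p = 2.34e-05). Sobic.004G293500 (chromosome 4, 62679601 to 62684198) fell from 40.4 ± 19.4 to 5.92 ± 3.36 CPM (adjusted p = 0.00115), and Sobic.010G168800 (chromosome 10, 49587343 to 49591316) fell from 63.1 ± 19.5 to 9.73 ± 5.47 CPM (adjusted p = 0.0019). In all 4733 genes passed, 2396 upward and 2337 downward (2324 and 2474 with RLE scaling, 1666 and 1708 without replicate 1 at 6 DAP), but those changed at least 2-fold were mostly upward, 762 against 109. With the replicate number as a block 5722 genes passed. Without replicate 2 of wild type at 7 DAP the count was 2659, and without replicate 1 or 2 of every group it was 2208 and 693, the latter without the call on Sobic.008G049200 (adjusted p = 0.0831, with 6.5e-41 to 0.0831 over all alternatives).

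From 7 to 8 DAP few genes were called in wild type: 27 passed, 8 upward and 19 downward. A low count of calls does not show that few genes changed. Sobic.010G164500 (chromosome 10, 48532984 to 48534594) rose from 1.91 ± 0.86 to 8.16 ± 1.05 CPM (adjusted p = 0.00533), and Sobic.002G341700 (chromosome 2, 70803028 to 70804730) from 10.4 ± 4.72 to 36.8 ± 4.45 CPM (adjusted p = 0.0266). Both calls were lost without replicate 2 at 7 DAP (adjusted p = 0.0822 for Sobic.010G164500 and 0.163 for Sobic.002G341700, with 1.35e-08 to 0.432 and 1.92e-08 to 0.499 over all alternatives). The call on Sobic.002G341700 was also lost without replicate 3 at 7 DAP (adjusted p = 0.0868), without replicate 1 or 2 at 8 DAP (0.0762 and 0.0707), without replicate 2 or 3 of every group (0.499 and 0.258) and with no low-count filter (0.0682). That on Sobic.010G164500 was also lost without replicate 1 or 2 of every group (0.0647 and 0.432). In a fit of the 6 libraries alone both were lost (0.129 each). The count depended on the fit, with 85 genes when the replicate number was a block, 137 by DESeq2, 148 by the exact test and 0 in a fit of the 6 libraries alone, where 1369 genes had an unadjusted p under 0.05. Leaving out single libraries gave between 4 (without replicate 2 at 7 DAP) and 57 genes (without replicate 1 at 7 DAP), with 6 without replicate 1 at 8 DAP and 46 without replicate 3 at 8 DAP, where the split turned to 27 upward and 19 downward. Without replicate 2 or 3 of every group it was 0 (1281 at an unadjusted p under 0.05) and 12. With all libraries 1681 genes reached that unadjusted p by edgeR, and a share of 0.05 of the tested genes would reach it with no difference.

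Over the whole interval from 6 to 8 DAP, 7012 genes passed in wild type, 3681 upward and 3331 downward (3495 and 3548 with RLE scaling). Again most of those changed at least 2-fold were upward, 1310 against 267. Sobic.001G438000 (chromosome 1, 64436899 to 64438301) rose from 0.142 ± 0.070 to 9.88 ± 6.12 CPM (adjusted p = 0.000128), and Sobic.002G278700 (chromosome 2, 66042386 to 66044804) rose from 0.415 ± 0.17 to 15.8 ± 7.18 CPM (adjusted p = 1.76e-06). Sobic.004G293500 fell further to 1.08 ± 0.48 CPM (adjusted p = 2.13e-05), and Sobic.010G168800 to 1.98 ± 1.39 CPM (adjusted p = 4.8e-05). The count was 4523 without replicate 1 at 8 DAP, and 3261 and 3507 without replicate 1 or 2 of every group.

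In phyB-1 from 6 to 7 DAP, 6638 genes passed, 3276 upward and 3362 downward (3671 and 3068 with upper quartile scaling). Without replicate 1, 2 or 3 at 7 DAP more genes were upward than downward (2487 and 2239, 2609 and 2288, 3640 and 3182), as among the 1094 changed at least 2-fold (625 and 469). Sobic.003G081900 (chromosome 3, 7026121 to 7027132) rose from 22.4 ± 7.50 to 257 ± 154 CPM, 11.4-fold (adjusted p = 0.000165), and Sobic.006G233500 (chromosome 6, 58470849 to 58477904) rose from 1.70 ± 0.65 to 13.7 ± 5.71 CPM (adjusted p = 0.000141). A pair of genes on chromosome 10 fell: Sobic.010G031100 (chromosome 10, 2517315 to 2518576) from 63.3 ± 25.5 to 3.78 ± 3.31 CPM (adjusted p = 0.000428), and Sobic.010G032000 (chromosome 10, 2572541 to 2573698) from 14.5 ± 5.55 to 1.08 ± 0.98 CPM (adjusted p = 0.00151). Leaving out replicate 2 of every group gave 3031 calls.

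From 7 to 8 DAP in phyB-1, Sobic.006G173000 (chromosome 6, 53822620 to 53826835) rose 19.9-fold from 0.804 ± 0.34 to 16.3 ± 4.75 CPM (adjusted p = 7.2e-05). Sobic.001G438500 (chromosome 1, 64483791 to 64485188) fell from 18.1 ± 6.42 to 2.25 ± 0.88 CPM (adjusted p = 0.00234). In all 1985 genes passed, 676 upward and 1309 downward, and 2990 with the replicate number as a block. Of the 168 called genes that changed at least 2-fold, 125 were upward and 43 downward. Leaving out any single library of these groups lowered this count. It was 1486, 154 and 922 without replicate 1, 2 or 3 at 8 DAP, and 1541, 1045 and 530 without replicate 1, 2 or 3 at 7 DAP. At an unadjusted p under 0.05 edgeR gave 3443 genes without replicate 2 at 8 DAP, against 5232 with all libraries. Fewer libraries give less power, so these removals do not decide how far the count rests on single libraries. Without replicate 2 or 3 of every group 1 and 61 genes passed (2692 and 3405 at an unadjusted p under 0.05 by edgeR). Without replicate 2 of every group the call on Sobic.001G438500 was lost (adjusted p = 0.17, with 1.19e-17 to 0.17 over all alternatives).

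From 6 to 8 DAP in phyB-1, 10647 genes passed, 5349 upward and 5298 downward (5168 and 5206 by DESeq2, 4841 and 4981 without replicate 1 at 6 DAP, 4610 and 4843 without replicate 3 at 6 DAP), the most of the 12 comparisons. Sobic.006G173000 had 2 reads over the 3 libraries at 6 DAP and 16.3 ± 4.75 CPM at 8 DAP, a ratio of 296 (95% counting interval 81.6 to 2450, adjusted p = 7.57e-08). Sobic.005G019800 (chromosome 5, 1834815 to 1835840) rose 24.8-fold from 0.713 ± 0.35 to 17.4 ± 5.46 CPM (adjusted p = 1.24e-06). Sobic.010G259800 (chromosome 10, 59458851 to 59460737) fell from 26.1 ± 3.42 to 1.39 ± 0.95 CPM (adjusted p = 1.32e-06). Of these calls, 2491 rose and 2730 fell in wild type over the same interval too, where 1002 and 898 would be shared by independent lists. Another 65 rose in phyB-1 and fell in wild type, and 141 fell in phyB-1 and rose in wild type.

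The last comparisons tested whether the change over days differed between genotypes. Between 6 and 8 DAP it differed for 2332 genes, with a more positive change in phyB-1 for 828 and a more negative one for 1504. Sobic.004G221900 (chromosome 4, 56493154 to 56494649) went from 2.01 ± 0.28 to 22.7 ± 3.85 CPM in phyB-1 and from 0.907 ± 0.17 to 0.326 ± 0.13 CPM in wild type (interaction log2 4.92 ± 0.62, adjusted p = 0.000158). Sobic.001G255700 (chromosome 1, 29399217 to 29402608) went from 2.99 ± 0.65 to 18.9 ± 1.79 CPM in phyB-1 and from 1.97 ± 1.60 to 0.875 ± 0.26 CPM in wild type (adjusted p = 0.00673). In the other direction, Sobic.006G243200 (chromosome 6, 59268679 to 59272280) went from 8.69 ± 1.79 to 0.61 ± 0.28 CPM in phyB-1 and from 14.3 ± 4.79 to 41.7 ± 27.6 CPM in wild type (interaction log2 -5.35 ± 1.06, adjusted p = 0.00741). Without replicate 3 of every group the calls on Sobic.001G255700 (adjusted p = 0.252, with 0.000418 to 0.252 over all alternatives) and Sobic.006G243200 (0.175, with 4.65e-07 to 0.175) were lost, and without replicate 2 of every group that on Sobic.001G255700 (0.0929). The most frequent classes were 523 genes that fell in phyB-1 without a call in wild type, 504 that fell in both but further in phyB-1, and 459 that rose in phyB-1 without a call in wild type. Leaving out single libraries gave between 1101 (without replicate 2 of phyB-1 at 8 DAP) and 2691 calls, with 1300 without replicate 3 of wild type at 8 DAP, 1338 without replicate 3 of wild type at 6 DAP, and 1467 and 1514 without replicate 3 of phyB-1 at 6 and 8 DAP. Without replicate 2 or 3 of every group 410 and 314 genes passed.

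Between 6 and 7 DAP the change differed for 247 genes, 69 more positive and 178 more negative in phyB-1. Sobic.010G031100, which fell in phyB-1, went from 77.1 ± 13.2 to 99.6 ± 4.53 CPM in wild type (interaction log2 -4.38 ± 0.79, adjusted p = 0.0188). Its neighbour Sobic.010G031200 went from 2.64 ± 1.52 CPM to 1 read in phyB-1 and from 8.27 ± 3.64 to 12.4 ± 3.40 CPM in wild type (adjusted p = 0.00733). The call on Sobic.010G031100 was lost without replicate 1 or 3 of phyB-1 at 7 DAP (adjusted p = 0.0538 and 0.0635) and without replicate 1, 2 or 3 of every group (0.183, 0.105 and 0.152, with 0.000306 to 0.183 over all alternatives), and that on Sobic.010G031200 without replicate 1 or 2 of every group (0.059 and 0.195, with 3.79e-05 to 0.195). The count was 159 without replicate 2 of phyB-1 at 6 DAP, 162 and 132 without replicate 2 or 3 of phyB-1 at 7 DAP, 123 without replicate 1 of wild type at 6 DAP, and 118 and 151 without replicate 1 or 2 of wild type at 7 DAP. It was 31, 25 and 68 without replicate 1, 2 or 3 of every group.

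Between 7 and 8 DAP 17 genes passed, 14 more positive and 3 more negative in phyB-1. Sobic.006G173000 was among them (interaction log2 4.38 ± 0.59, adjusted p = 0.00625), with 2.28 ± 1.15 CPM at 7 DAP and 2.17 ± 1.02 CPM at 8 DAP in wild type. That call was lost without replicate 2 of wild type at 7 DAP (adjusted p = 0.0559) and without replicate 2 or 3 of every group (0.327 and 0.613, with 7.01e-08 to 0.613 over all alternatives). The count was 65 with the replicate block and 124 by DESeq2. It was 11, 6 and 6 without replicate 1, 2 or 3 of phyB-1 at 7 DAP, 3 and 2 without replicate 2 or 3 of phyB-1 at 8 DAP, 70, 0 and 2 without replicate 1, 2 or 3 of wild type at 7 DAP, and 29 and 2 without replicate 1 or 3 of wild type at 8 DAP. Without replicate 1, 2 or 3 of every group it was 100, 0 and 0. At an unadjusted p under 0.05 edgeR gave 974 and 790 genes without replicate 2 or 3, against 2155 with all libraries. A share of 0.05 of the tested genes would reach that p with no difference, and neither count clearly exceeds that share.

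The authors' deposited table tests single transcripts. It holds fewer calls than transcript-level tests here in 8 comparisons of 2 groups, and more for wild type at 8 against 7 DAP, with 18 transcripts against 4 here. At a corrected p under 0.05, the authors' deposited table holds 252 transcripts between genotypes at 6 DAP, 660 at 7 DAP and 1542 at 8 DAP. At 6 DAP the deposited calls cover 119 genes higher in phyB-1, of which 93 were also called higher here, and 128 lower, of which 119 were also called lower here, while 5 were called here in the opposite direction. At 8 DAP the authors' deposited table has 517 genes higher in phyB-1, of which 506 were also called higher here, and 998 lower, of which 985 were also called lower here, while 4 were opposite. For wild type at 8 against 7 DAP 1 of 6 higher and 3 of 11 lower genes in the deposited calls were also called here.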

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

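The tests of depth, of left-out libraries, of held-out replicates, of the spread of each day alone, of the spread under exchange and of the splits that part replicate pairs were chosen after the results were seen, while the first comparison of standard errors and the splits of the libraries were set before. The results listed first are those where the change over days differed between genotypes by an interaction test.

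The change from 6 to 8 DAP differed between genotypes for 2332 genes, from 6 to 7 DAP for 247 and from 7 to 8 DAP for 17. For each, 82 arrangements were fitted, the real one and those in which 1 library of each genotype changed places on both days. Only the real arrangement reached its count (1 of 82 in each case), and the highest other counts were 0 for 8 against 6 DAP, 1 for 7 against 6 DAP and 0 for 8 against 7 DAP. The exchanged libraries mix genotypes within a group, and the common biological coefficient of variation was at least 17.4%, 21.1% and 19.2% under exchange for 7 against 6, 8 against 7 and 8 against 6 DAP, against 11.1% in the real arrangement. Exchange also dilutes the genotype difference. Low counts can come from either, and which lowered them was not tested, so these arrangements do not decide whether chance is excluded.

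The count of genes called between genotypes rose from 2473 at 6 DAP to 5687 at 7 DAP and 8475 at 8 DAP. Depth does not account for it, since with all libraries thinned to one total the count at 8 DAP was still 3.57 times that at 6 DAP. Without the outlying replicate 2 of phyB-1 at 6 DAP the 6 DAP count was 1951. Leaving out any single library of 6 DAP lowered that count (to between 1662 and 2178), so this removal cannot decide whether the outlier matters. The median standard error of genes with a mean of at least 5 CPM was 1.02 times as high at 6 DAP as at 8 DAP, but a spread shared by all groups fixes that ratio near 1 and it decides nothing. With each day fitted from its own 6 libraries the ratio was 1.04, which argues against noisier libraries at 6 DAP, and the counts were 1926 at 6 DAP and 7995 at 8 DAP. Over these 14775 genes the median absolute log2 fold change was 0.13, 0.21 and 0.27 at 6, 7 and 8 DAP, and 405, 657 and 991 differed at least 2-fold, so the measured difference widened; that it did so as the buds developed is a hypothesis, and a shift in the cell types or neighbouring tissue collected with a bud was not tested.

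From 7 to 8 DAP phyB-1 had 1985 calls and wild type 27, yet the test of the difference called only 17 genes. Without the outlying replicate 3 of wild type at 8 DAP there were 46 wild-type calls. By edgeR, 2813 genes then had an unadjusted p under 0.05, against 1681 with all libraries and 974 and 1703 without replicate 1 or 2. A fit with fewer libraries has less power, so this removal does not decide how far the spread in wild type is a cause. Part of the contrast may rest on single phyB-1 libraries: without replicate 2 at 8 DAP the phyB-1 count was 154, though leaving out any single phyB-1 library of 7 or 8 DAP lowered it. A smaller change in wild type over the same genes is also consistent with the data: when genes were called from 2 phyB-1 replicates, with the replicate number as a block, the median wild-type change was at most 46.1% of the change in the phyB-1 libraries held out (17.2% and 26.6% in the other rounds, over 2652, 63 and 343 genes). Without the block the rounds left 1399, 1 and 27 genes, and all of these explanations stay open.

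For the comparisons of 2 groups, 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many calls in each of the 9, and the highest count of any other split was 2 for phyB-1 at 7 against 6 DAP and 0 in the other 8 comparisons. The other splits mix the groups, which dilutes the difference between them. The common biological coefficient of variation under them was at least 12.3% in 8 comparisons, against 11.1% in the real split. It went down to 10.9% for wild type at 8 against 7 DAP, which had 27 calls in the real split. Whether the dilution or the spread lowered the counts was not tested. In the 5 comparisons where replicate numbers pair the libraries, 4 of the 10 splits part all 3 pairs, the real one included, and the others of these 4 gave 0 calls, while the remaining splits put both libraries of a pair into one group.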

How the results depend on the processing

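Transcript-level testing, thinning to the smallest library, leaving out one replicate number in every group and fitting the 4 groups of an interaction alone were chosen after seeing the data, and the other settings before. Counts are given in the order phyB-1 against wild type at 6, 7 and 8 DAP, then 7 against 6, 8 against 7 and 8 against 6 DAP in phyB-1, the same 3 in wild type, and the same 3 interactions. Scaling by RLE or upper quartile, both filters, the index-set covariate, unique reads and thinning left all 12 counts within 1.5 times. No scaling moved the median log2 fold change by over 0.1, but upper quartile scaling moved the share of higher genes for 8 against 7 DAP in phyB-1 from 34.1% to 47.7%. Which direction held more genes turned under at least 1 scaling or count model in 7 comparisons, all of the 9 between 2 groups except 8 against 7 DAP in phyB-1 and in wild type.

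With a log2 fold change of at least 1 as well, the counts were 975, 1638, 2316, 1094, 168, 2979, 871, 15, 1577, 176, 11 and 817, since this adds a criterion. With the replicate block, 8 against 7 DAP gave 2990 in phyB-1 and 85 in wild type, and the interactions of 7 against 6 and 8 against 7 DAP gave 383 and 65. At transcript level, 8 against 7 DAP gave 856 in phyB-1 and 4 in wild type, and the interactions 76, 0 and 1102 (7 against 6, 8 against 7 and 8 against 6 DAP). The exact test gave 3343 and 148 for 8 against 7 DAP in phyB-1 and wild type. DESeq2 gave 137 for 8 against 7 DAP in wild type, and 536 and 124 for the interactions of 7 against 6 and 8 against 7 DAP. With only the groups compared, edgeR gave 0 for 8 against 7 DAP in wild type (1369 at an unadjusted p under 0.05) and 9 for the interaction of 8 against 7 DAP. The cause was not tested for these settings.

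Without single libraries or whole replicate numbers, the counts ran from 1053 to 2178, 2722 to 5202, 5116 to 8277, 3031 to 6822, 1 to 1877, 7554 to 10091, 693 to 4339, 0 to 57, 3261 to 7793, 25 to 315, 0 to 100 and 314 to 2691. The cause was not tested. Of the named genes, phyB (Sobic.001G394400) reversed its sign in wild type, where no change was called. With libraries or replicate numbers left out, its log2 fold change in wild type ran from -0.0471 to 0.131 at 7 against 6 DAP, from -0.0700 to 0.0640 at 8 against 7 DAP and from -0.0227 to 0.174 at 8 against 6 DAP. No other named gene reversed under any setting. The planned tests of gene lists were not run, since the lists had no members.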

Other observations

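The tests of gene placement and of shared reads were chosen after the positions of the genes were seen. The test of the wider segment was written before its result. Together with the 4 genes described above, 12 genes were read in one genotype alone, defined after seeing the data as at least 1 CPM in all 9 libraries of one genotype and at most 0.2 CPM in all 9 of the other. Of these, 10 were read in phyB-1 alone and 2 in wild type alone. They include Sobic.001G270000 (chromosome 1, 44644335 to 44645136), with 501 reads in phyB-1 and 2 in wild type, and Sobic.004G136700 (chromosome 4, 35280945 to 35283277), with 481 and 6.

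Of these 12 genes 3 lie within 2 Mb of phyB. Sobic.001G375900 (wild type alone) and Sobic.001G376100 (phyB-1 alone) start 1.62 and 1.58 Mb before it, and Sobic.001G418300 (wild type alone) starts 1.89 Mb after it. Only 333 of the 19655 tested genes lie that close, and a share of 0.00102 of 100000 random draws of 12 tested genes placed as many there. That window was chosen after these positions were seen, and with genes within 100 kb counted as 1 locus, 2 of 11 loci lie within 2 Mb and the share was 0.0137, and within 5 Mb it was 0.066, so chance placement stays open. Within 5 Mb of phyB, 95 of 761 tested genes (12.5%) were called in the same direction on all 3 days, against 7.71% elsewhere, a ratio of 1.62. That lies between the ratios of 2 and 1.2 set beforehand for and against a linked segment that differs between the lines. Of all windows of as many neighbouring genes, 1.14% held as many such genes. These windows overlap one another and include those around phyB, so this share does not measure chance. A segment inherited with the phyB-1 allele may contribute, but it cannot be told apart here from regulation by phyB. Such a segment on chromosome 1 would not cover those of the 12 genes on chromosomes 2, 3, 4, 5, 6, 8 and 10. The sample titles give each genotype its own line code, so genotype and line coincide in all libraries. Differences between the lines elsewhere in the genome were not tested. They cannot be told apart from regulation by phyB, in these genes or in any comparison between genotypes. Reads shared between similar copies cannot be told apart either: 9 of the 12 genes kept at least 90% of their reads in the unique column, but that column separates only transcripts of one gene.

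Sobic.001G438000, which rose in wild type from 6 to 8 DAP, had at most 7 reads in any phyB-1 library (0.322 ± 0.109 CPM at 8 DAP, SD, n = 3).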
